A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

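The series holds 3 two-colour arrays of baker's yeast total RNA. Per the labels, each array carried RNA of a yap1 deletion mutant labelled with Cy3 and RNA of the wild type labelled with Cy5, both from cells exposed to 0.2 mM As(III) for 1 h. The labels number the arrays as replicates 1 to 3 of this single comparison, and all 3 have the same dye orientation, so a dye effect of a gene cannot be separated from a difference between the strains.

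The deposited table holds 1 log ratio per spot and array, treated here as a log2 ratio of the channels of that array. The base of the logarithm, the direction of the ratio, the scanner software, the background correction and any normalization by the authors were not given in the sources used here. The values ran from −6.13 to 1.39, −6.77 to 1.25 and −5.47 to 1.45 on replicates 1, 2 and 3, a range too wide for log10 of scanner intensities, and log2 or natural log could not be told apart. The column medians over spots were −2.13, −2.37 and −1.61, so the deposited values were not centred on 0. No fold change is given because the base is open: if the values were natural logs, each would be a larger change. Channel intensities and spot quality were not analysed here, so signal over background is not known for any spot.

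Spots were named through the platform annotation supplied with the table. Of 13056 spots, 11138 had 1 gene symbol, 0 had several and 1918 (14.7%) had none; these last are unnamed here, which does not say that they hold no probe. The symbols covered 5539 genes, of which 5534 were found in the RefSeq gene table of yeast, assembly R64, which was used for locus names and for the neighbours of YAP1 only. In that table the short gene MIN4 lies between ERG6 and YAP1. Repeated spots of a gene were averaged: 5510 genes had 2 spots, 28 had 4 and 1 had 6. Spots lay in 48 blocks of 272. At 6 positions of the block there was no gene symbol in any block, and at 4 of these, with 192 spot pairs, the ratios were low. Repeated spots correlated across pairs with a Pearson coefficient of 0.741, 0.809 and 0.716 on the 3 arrays, and the SD between repeated spots was 0.460, 0.420 and 0.400. Differences between blocks held 6.67, 9.74 and 3.06% of the variance.

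Each array was centred on its median over genes. The mean log ratio of the 3 arrays was tested against 0 with limma (lmFit with an intercept, eBayes; two-sided), with Benjamini-Hochberg adjustment over the 5539 genes and a threshold of 0.05. The prior had 13.3 degrees of freedom, and the median SD between arrays was 0.359. The smallest absolute mean among called genes was 0.63. The correlation of log ratios was computed across genes for each pair of arrays.

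Before the data were examined, 27 gene lists were written from textbook knowledge: Yap1 targets, peroxide and thiol defence, aryl alcohol and old yellow enzyme type oxidoreductases, drug transporters, arsenite detoxification, sulfate assimilation and methionine, cysteine and glutathione synthesis, pentose phosphate and NADPH, proteasome, chaperones, general stress, ribosome biogenesis, ribosomal proteins, iron, copper and zinc, respiratory chain, glycolysis, ergosterol synthesis, Gcn4-controlled amino acid synthesis, phosphate regulon, histones, pheromone and mating type, cell cycle, strain markers, the Yap family, the neighbours of YAP1, and subtelomeric families. The 26 lists with at least 5 measured members were tested with camera (preset correlation 0.01, two-sided), adjusted over the lists; the neighbours of YAP1 were given gene by gene. Some genes stand in several lists.

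The rule for named genes was also fixed before the data were examined. It takes YAP1, the 12 genes farthest out on each side among those past the threshold with the same sign on all arrays, up to 4 called members of each list with the largest absolute mean (or up to 2 members where none was called), all arsenite detoxification genes, all strain markers, and ERG6 and GIS4. Genes named to complete a small count outside this rule were chosen after their values were seen, as said where they appear.

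The direction rule was fixed before the data were examined as well: the ratio would be read as mutant over wild type only if YAP1 lay well below 0 on all arrays, and turned if it lay well above 0. No direction was to be given if YAP1 was missing or went both ways. The rule set no number for well below 0. YAP1 had deposited values of −3.54, −2.52 and −2.33 as means of its 2 spots, but nearly all genes lay below 0 as deposited. After centring, these means lay below 0 on all arrays, but only at −0.22 on replicate 2. This was not taken as well below 0, so no direction is given, a judgement made after the values were seen.

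The fit was tested on simulated data of 3 arrays and 5539 genes, 200 of them shifted. In this simulation, 0% of shifts of 0.5 units, 52.2% of shifts of 1 unit and 100% of shifts of 2 units were called, with 2 unshifted genes called. Camera called 5 of 5 shifted lists and 0 of 15 unshifted lists. The simulated genes were drawn independently, with no dye, brightness or scatter trend. The simulation therefore does not show how these tests behave with correlated genes or with such trends. Only 200 genes were shifted, while 28.5% of the genes were called in the data. The adjusted threshold depends on that share, so the percentages called are not the sensitivity reached in the data.

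Alternatives planned before the data were examined were values as deposited, scaling of the arrays to a common median absolute deviation, leaving out each replicate, genes with a value on 2 or more arrays, centring on genes outside the ribosomal lists, robust eBayes, an unmoderated one-sample test, array weights, the median over spots, every spot on its own, other thresholds, an estimated correlation in camera, fry, lists without members of other lists, the sign of all arrays turned, and correlations without called genes. Alternatives chosen after the data were seen were centring of each block, centring on the 4 low positions without a gene symbol, removal of a loess trend of the ratio on the scatter between repeated spots, and leaving out ribosomal protein genes. The versions used were R 4.3.3, limma 3.58.1, statmod 1.5.0, and matplotlib 3.10.9 for the plots.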

Results

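Each of the 3 arrays compared, on 1 slide, RNA from a baker's yeast strain lacking YAP1 with RNA from wild type, both from cells exposed to 0.2 mM arsenite, As(III), for 1 h. Yap1 is a transcription factor that activates genes of antioxidant defence and detoxification, so the comparison asks which transcripts differ between the strains in arsenite-stressed cells. The table used here gave a log ratio for each of 13056 spots on every array, with no missing value. Of these spots, 11138 carried a gene symbol and covered 5539 genes, 5510 of them with 2 spots each. The median over spots was −2.13, −2.37 and −1.61 on replicates 1, 2 and 3. The titles name the mutant before the wild type, while the labels put the mutant in Cy3 and the wild type in Cy5. Whether the ratio follows the order of the titles or is Cy5 over Cy3 was not given in the sources used here, nor was the base of the logarithm. Values are therefore on the deposited log scale minus each array's median over genes (−2.11, −2.30 and −1.59), and a gene is said to lie on the high side or on the low side of that median, with no statement of which strain held more transcript. As deposited, 98.4, 98.9 and 96.9% of the genes had a ratio below 0. The labels do not say whether the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

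YAP1 (YML007W), the deleted gene, lay on the low side of all 3 arrays as the average of its 2 spots, at −1.43, −0.22 and −0.74, with a mean of −0.80 ± 0.61 (SD, n = 3) and a limma adjusted p of 0.0323. The 2 spots differed, with deposited values of −4.125 and −2.95, −2.99 and −2.06, and −2.88 and −1.79 on replicates 1, 2 and 3. The first lay below the array median on every array, while on replicate 2 the second lay above that median of −2.30. On replicates 1, 2 and 3 the YAP1 average stood at the 2.47th, 39.5th and 9.48th percentile of the genes, so on replicate 2 it was close to the middle of the array. ERG6, a sterol methyltransferase gene of ergosterol synthesis on one side of YAP1, lay on the high side at 1.09 ± 0.45 (SD, n = 3), with an adjusted p of 0.00451. GIS4, the gene on the other side, lay on the low side at −0.85 ± 0.48 (SD, n = 3), with an adjusted p of 0.0197. The YAP1 mean fell within the values of 192 spot pairs without a gene symbol at 4 fixed block positions, whose median was −1.05, and stood at their 75th percentile. It was no longer past the threshold without replicate 1 (−0.48, adjusted p = 0.226) or without replicate 3 (−0.83, adjusted p = 0.197), and set against those 192 pairs it had a mean of 0.23, so the values of the deleted gene did not settle the direction of the ratio. Here and below, a value against these pairs is the value minus their median on each array, and the spread among the pairs is left out.

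On the high side, genes of the translation machinery stood farthest from the median. RPS28A, for a protein of the small ribosomal subunit, lay at 2.77 ± 0.12, RPL1B at 2.65 ± 0.22, RPS29B at 2.60 ± 0.09 and RPL41A at 2.57 ± 0.05 (SD, n = 3 each), all with a limma adjusted p of 7.76e-06. Of the 12 genes farthest out on this side, 10 encode ribosomal proteins: beside those 4 they are RPS31 (2.57), RPS17A (2.51), RPL24B (2.50), RPL15A (2.49), RPL22A (2.46) and RPL37A (2.46). The remaining genes were YBR138C, an uncharacterised open reading frame, at 2.68 ± 0.48 (SD, n = 3), and TMA19, which encodes a ribosome-associated protein, at 2.56 ± 0.32 (SD, n = 3).

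On the low side, ARR2, the arsenate reductase gene, was the lowest of the 5539 genes at −2.47 ± 0.71 (SD, n = 3; adjusted p = 1.17e-05). It was followed by HSP12, a small stress protein gene, at −2.25 ± 0.65, and by CUP1-2, a copy of the copper metallothionein gene, at −2.0 ± 0.58 (SD, n = 3 each). CTT1, the cytosolic catalase gene, came next at −1.86 ± 0.23, ahead of CUP1-1, the other metallothionein copy, at −1.83 ± 0.59 (SD, n = 3 each). PRX1, the mitochondrial peroxiredoxin gene, lay at −1.79 ± 0.41, and MET3, the ATP sulfurylase gene, at −1.74 ± 0.36 (SD, n = 3 each). The rest of the 12 lowest were YLR001C (−1.79), PRM1 (−1.69 ± 1.33 SD, with −0.25 on replicate 1), HOM2 (−1.66), TEL1 (−1.62) and DUG2 (−1.59). The adjusted p of these 12 genes was between 1.17e-05 (ARR2) and 0.00305 (PRM1).

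**Figure D1:**
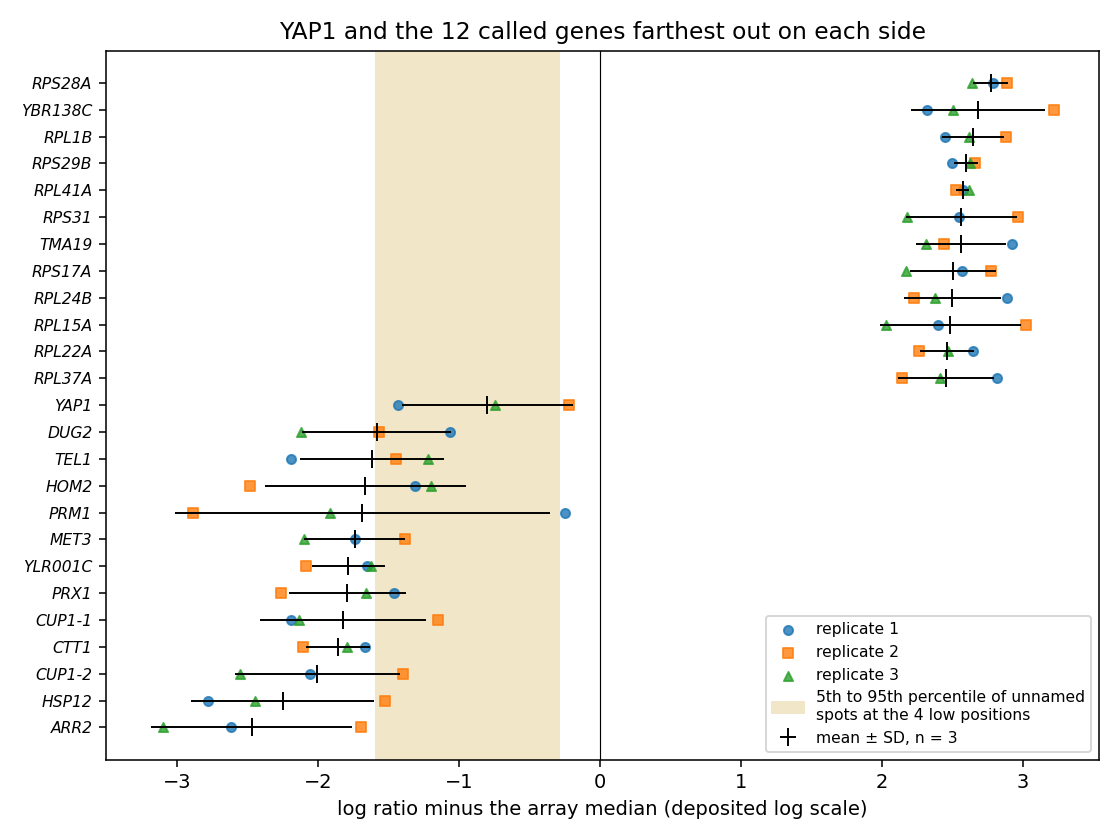
Log ratio of YAP1 and of the 12 called genes farthest out on each side, minus the array median and on the deposited log scale, with 1 symbol per array, the mean and the SD over 3 arrays, and a band for the 5th to 95th percentile of unnamed spots at 4 block positions. The 12 high-side genes have means from 2.46 to 2.77, YAP1 lies inside the band at −0.80, and ARR2 (−2.47), HSP12 (−2.25) and CUP1-2 (−2.0) lie farthest below it.

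In all, 1581 of 5539 genes (28.5%) passed an adjusted p of 0.05 in limma, 886 on the high side and 695 on the low side, and 2261 had an unadjusted p under 0.05. A mean of at least 1 unit was reached by 486 of the high-side and 221 of the low-side genes. The sign was the same on all 3 arrays for 3265 genes (58.9%, where chance gives 25%). The log ratios of the array pairs correlated across genes with a Pearson coefficient of 0.631 (replicates 1 and 2), 0.623 (1 and 3) and 0.736 (2 and 3), and Spearman coefficients of 0.601, 0.574 and 0.696. These are correlations across genes, which are not independent replicates, and among the genes that did not pass the threshold the Pearson coefficients were 0.149, 0.081 and 0.401. The number of genes called was 889 without replicate 2 and 323 without replicate 3 (275 high, 48 low), and the split into sides rested on the centring: as deposited, 2 genes were called high and 5258 low, and against the 192 pairs without a gene symbol 4170 were high and 10 low.

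The ratio moved with the scatter between the repeated spots of a gene. Among 10 groups of genes ordered by this scatter, the median ratio was 0.60 in the group with the smallest scatter, or 0.48 without the ribosomal protein genes. It was lower in each group with larger scatter, down to −0.54. The table used here held no channel intensities, so spot brightness itself was not analysed here. The spots without a gene symbol at 4 block positions lay lower still, and 692 of the 695 low-side genes lay within their range. Only ARR2, HSP12 and CUP1-2 lay below their 1st percentile of −1.87. In a limma test against the median of those spots on each array, which leaves out their own spread, 10 genes were lower: ARR2 by −1.44, HSP12 by −1.22, CUP1-2 by −0.98, CTT1 by −0.83, CUP1-1 by −0.80, PRX1 by −0.77, YLR001C by −0.76, MET3 by −0.71, PRM1 by −0.66 and HOM2 by −0.64. All but the first 3 lay within the range of those spots. The scatter between repeated spots was large for PRM1 (1.395), HOM2 (1.055), YLR001C (0.787) and ARR2 (0.785), against 0.409 over all genes. For the rest of the 10 it was at most 0.48 (MET3).

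**Figure D2:**
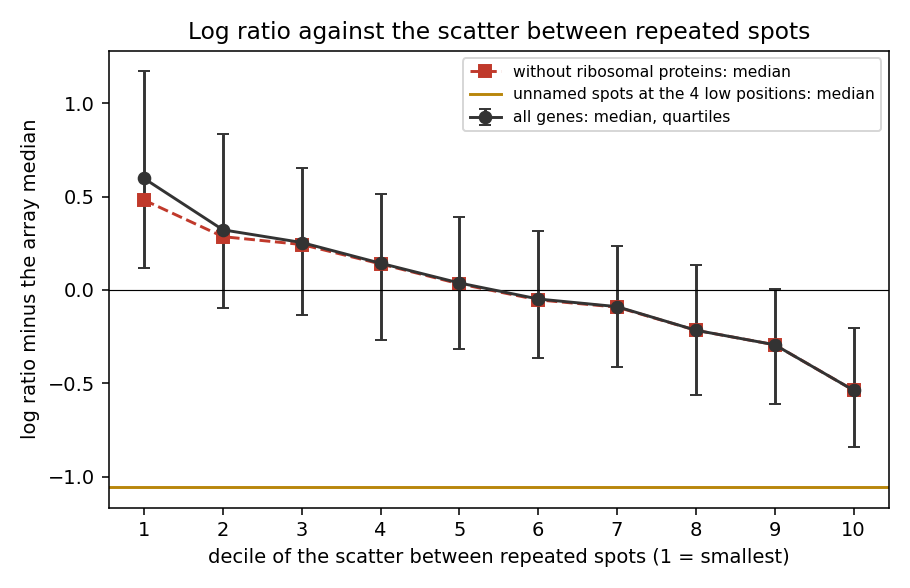
Median log ratio of the genes, minus the array median and on the deposited log scale, in 10 groups of genes ordered by the scatter between repeated spots, with quartiles as bars and the median without ribosomal protein genes as a dashed line. The median runs from 0.60 at the smallest scatter to −0.54 at the largest, and the unnamed spots at 4 block positions lie at −1.05.

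Gene lists written before the data were examined were compared with all other genes by camera, limma's test of a gene set, with a preset correlation of 0.01 between genes. Of 26 lists tested, 7 passed an adjusted p of 0.05, 5 on the high side and 2 on the low side. None of the 26 passed when the correlation between genes was estimated from the data, by which the smallest adjusted p was 0.0865. With an estimated correlation, camera takes its degrees of freedom from the arrays and not from the number of genes, so hardly any list can pass. Here and below, an adjusted p with an estimated correlation therefore does not decide whether a list is displaced. The estimated correlation was 0.0093 for ribosomal proteins and −0.048 for copper and zinc, both below the preset value. For these lists a larger correlation was therefore not what removed the call. In the other lists that had passed, the estimate ran from 0.011 (ribosome biogenesis) to 0.31 (glycolysis). By fry, limma's test of whether the members of a list move 1 way on balance, 4 lists passed. Set against the 192 pairs without a gene symbol in place of the array median, all 26 lists had a median above 0.

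The ribosomal protein genes formed the most displaced list. Of 132 measured, 125 lay on the high side, 2 on the low side and 5 did not pass, and the counts were also 125 and 2 when adjusted over the list alone. Their median was 2.07, and it was 2.09, 2.13 and 2.03 on the 3 arrays (camera adjusted p = 1.54e-61, and adjusted p = 0.0865 with an estimated correlation). RPS19A (−1.50) and RPS30A (−0.92) were the low-side members, and RPL19A, RPL26B, RPL36A, RPL41B and RPL43B did not pass; these 7 were named after their values were seen. As deposited, with no centring, the median of the list was 0.07. Many ribosomal protein genes exist as near-identical pairs, whose spots can take up each other's RNA, so values of single paralogs are uncertain.

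Genes of ribosome assembly lay on the same side with a smaller displacement. Of 80 ribosome biogenesis genes, 29 lay on the high side, 2 on the low side and 49 did not pass (34 and 3 adjusted over the list alone). The snoRNP protein genes NOP56 and GAR1 lay at 1.41 ± 0.60 and 1.41 ± 0.23, the nucleolin-like gene NSR1 at 1.32 ± 0.25 and ERB1 at 1.30 ± 0.31 (SD, n = 3 each). DBP10 (−0.85) and UTP22 (−0.75), named after their values were seen, were the low-side members. The list median was 0.49, and −1.51 as deposited with no centring (camera adjusted p = 2.86e-05, and adjusted p = 0.589 with an estimated correlation). Without replicate 3, 4 members were called high and 0 low.

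The lists of glycolysis, Gcn4-controlled amino acid synthesis and histones also lay toward the high side of the array median. Of 25 glycolysis genes, 15 passed on the high side and 0 on the low side (16 and 0 adjusted over the list alone), led by the pyruvate kinase gene CDC19 (1.76 ± 0.53), the aldolase gene FBA1 (1.72 ± 0.25), TDH2 (1.71 ± 0.39) and the enolase gene ENO2 (1.66 ± 0.62; SD, n = 3 each). Their median was 0.94, and −1.06 as deposited (camera adjusted p = 1.29e-06, and adjusted p = 0.647 with an estimated correlation). Of 43 amino acid synthesis genes controlled by Gcn4, 23 lay on the high side, 1 on the low side and 19 did not pass (24 and 2 adjusted over the list alone). The homocitrate synthase gene LYS21 (1.83 ± 0.24), the aminotransferase gene BAT1 (1.58 ± 0.49), THR4 (1.54 ± 0.34) and LEU1 (1.51 ± 0.54) led them (SD, n = 3 each), and ARG7 (−1.46), named after its value was seen, was the low-side member. The median of this list was 0.85, and −1.15 as deposited (camera adjusted p = 1.13e-05, and adjusted p = 0.647 with an estimated correlation). Its high-side calls numbered 15 without replicate 2 and 9 without replicate 3. Of 10 histone genes, 5 lay on the high side and 5 did not pass (5 and 0 adjusted over the list alone): the histone H4 genes HHF2 and HHF1 lay at 2.29 ± 0.32 and 2.10 ± 0.17, the histone H3 genes HHT1 and HHT2 at 2.00 ± 0.61 and 1.95 ± 0.38 (SD, n = 3 each), and HTZ1 at 1.01, the last named after its value was seen. The histone median was 0.77, and −1.23 as deposited (camera adjusted p = 0.00403, and adjusted p = 0.609 with an estimated correlation). HHF1 and HHF2, HHT1 and HHT2, TDH2 and its paralogs, and CUP1-1 and CUP1-2 are close or identical copies, and the PAU and COS families share sequence, so their single values are uncertain in the same way.

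Genes of the general stress response, controlled by Msn2 and Msn4, lay toward the low side. Of 38 measured, 14 lay on the low side, 4 on the high side and 20 did not pass (15 low and 5 high adjusted over the list alone). HSP12 (−2.25) and CTT1 (−1.86) were followed by MSC1 at −1.43 ± 0.94 and by SOL4, a lactonase gene of the pentose phosphate pathway, at −1.30 ± 0.20 (SD, n = 3 each). TPS1 (1.12), which encodes trehalose phosphate synthase, HOR7 (1.12), ROQ1 (0.70) and GPP2 (0.70), named after their values were seen, were the high-side members. The list median was −0.45, and 0.58 against the 192 pairs without a gene symbol (camera adjusted p = 0.0204, and adjusted p = 0.647 with an estimated correlation). Against those pairs 19 members were called high and 2 low. The call of this list was also lost without replicate 3 (adjusted p = 0.157, with 2 members low and 1 high), with values as deposited (adjusted p = 0.0945) and when genes of other lists were left out (adjusted p = 0.114).

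Of 15 copper and zinc genes, 4 lay on the low side, 0 on the high side and 11 did not pass (4 and 0 adjusted over the list alone). They were CUP1-2 and CUP1-1, CRS5, a further metallothionein gene, at −0.92 ± 0.50, and MAC1, for the transcription factor of copper uptake, at −1.37 ± 0.76 (SD, n = 3 each). The zinc transporter genes did not pass, with ZRT1 at −0.70, ZRT2 at 0.33 and ZRT3 at 0.08, named after their values were seen. The median of the list was −0.44, and 0.59 against the 192 pairs without a gene symbol (camera adjusted p = 0.0196, and adjusted p = 0.609 with an estimated correlation). As deposited, the list was not past the threshold (adjusted p = 0.115), and without replicate 3 only 1 member was called low.

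**Figure D3:**
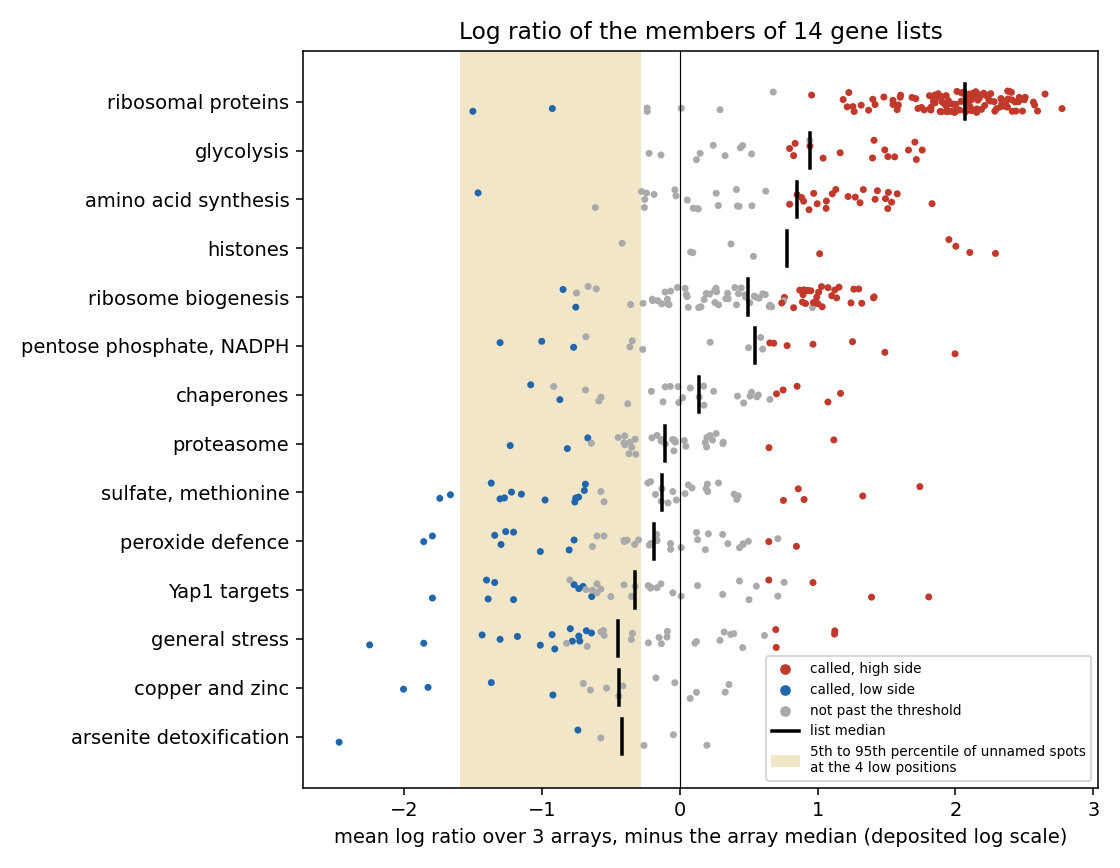
Mean log ratio over 3 arrays, minus the array median and on the deposited log scale, of each measured member of 14 gene lists, with called genes in colour, the list median as a bar and a band for the 5th to 95th percentile of unnamed spots at 4 block positions. The ribosomal protein list has its median at 2.07 and glycolysis at 0.94, while general stress (−0.45) and copper and zinc (−0.44) lie below 0; against the unnamed spots the medians of these last lists are 0.58 and 0.59.

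Genes described as depending on Yap1 in oxidative or metal stress went both ways. Of 37 measured, 9 lay on the low side, 4 on the high side and 24 did not pass (13 low and 5 high adjusted over the list alone). On the low side, PRX1 (−1.79) was followed by FRM2, an oxidoreductase gene, at −1.40 ± 0.12 (SD, n = 3). On the high side stood AAD4, an aryl alcohol dehydrogenase gene, at 1.81 ± 0.29, and FLR1, a drug efflux transporter gene, at 1.39 ± 0.35 (SD, n = 3 each), with TAL1 (0.97) and the thioredoxin reductase gene TRR1 (0.65) named after their values were seen. The list median was −0.32, and 0.70 with 21 members high and 1 low against the 192 pairs without a gene symbol. The list did not pass (camera adjusted p = 0.0838, and adjusted p = 0.647 with an estimated correlation), and without replicate 3 only 2 members were called low and 2 high. It passed without replicate 1 (adjusted p = 0.0427) and, in a setting chosen after the data were seen, when the trend with the scatter between repeated spots was removed (adjusted p = 0.0106, and adjusted p = 0.427 with an estimated correlation).

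Genes of peroxide and thiol defence had 9 of 38 members on the low side and 2 on the high side (10 and 3 adjusted over the list alone). Beside CTT1 (−1.86) and PRX1 (−1.79) the low members included the glutathione transferase gene ECM4 (−1.34 ± 0.73) and the glutaredoxin gene GRX8 (−1.30 ± 0.64; SD, n = 3 each), while TRX1 (0.85) and TRR1 (0.65), named after their values were seen, lay on the high side. The median was −0.19, and 0.84 against the 192 pairs without a gene symbol (camera adjusted p = 0.0567). Of 22 aryl alcohol and old yellow enzyme type oxidoreductase genes, 6 lay on the low side and 1, AAD4, on the high side (7 and 1 adjusted over the list alone), with GCY1 at −1.53 ± 0.50 and AAD15 at −1.20 ± 0.49 (SD, n = 3 each). Their median was −0.36, and 0.66 against the same pairs (camera adjusted p = 0.0567). With an estimated correlation both lists had an adjusted p of 0.686. Both passed in some other settings, given with the alternatives, while without replicate 3 the low-side calls were 3 in the defence list and 0 in the oxidoreductase list.

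Of the genes that handle arsenic, ARR2 (−2.47) and ARR3, the arsenite exporter gene, at −0.74 ± 0.19 (SD, n = 3; adjusted p = 0.0262) lay on the low side. The other members of this list of 6 did not pass: YCF1, for the vacuolar transporter of glutathione conjugates, lay at −0.57 ± 0.37, ARR1, for the transcription factor that activates its neighbours ARR2 and ARR3, at −0.26 ± 0.23, FPS1, for the glycerol channel that admits arsenite, at −0.05 ± 0.13, and the kinase gene HOG1 at 0.20 ± 0.25 (SD, n = 3 each). The same 2 genes passed when adjusted over the list alone. Only 1 member was called low without replicate 2, and likewise without replicate 3. The list median of the means over 3 arrays was −0.42, and 0.61 against the 192 pairs without a gene symbol. On replicates 1, 2 and 3 the list median was −0.49, −0.59 and −0.13. The list did not pass camera (adjusted p = 0.0838, and adjusted p = 0.647 with an estimated correlation). It passed without replicate 2 (adjusted p = 0.0309), and in settings chosen after the data were seen with blocks centred (adjusted p = 0.0272) and with values centred on those pairs (adjusted p = 0.0440). In that last setting camera still compared the list with the other genes, not with the pairs, and the list lay on the low side of the other genes. It also passed by fry (adjusted p = 0.0235).

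Sulfate assimilation and methionine genes were split. Of 38, 13 lay on the low side and 5 on the high side, with the same counts adjusted over the list alone. MET3 (−1.74), HOM2 (−1.66 ± 0.71) and MET16, the PAPS reductase gene, at −1.37 ± 0.44 lay low, and SAH1, for S-adenosylhomocysteine hydrolase, lay high at 1.74 ± 0.51 (SD, n = 3 each). MET13 (1.33), JLP1 (0.90), MET12 (0.86) and MET32 (0.75), named after their values were seen, were the rest of the high-side members. The median was −0.13, and 0.90 with 23 members high and 2 low against the 192 pairs without a gene symbol. The list did not pass (camera adjusted p = 0.0952, and adjusted p = 0.693 with an estimated correlation) except in settings given with the alternatives, and without replicate 3 only 1 member was called low and 2 high. Of 14 genes of cysteine and glutathione synthesis and turnover, 5 lay on the low side and 1 on the high side (the same counts adjusted over the list alone), with DUG2 at −1.59 ± 0.53, STR3 at −1.15 ± 0.22, STR2 at −0.77 ± 0.37 and DUG3 at −0.75 ± 0.50 (SD, n = 3 each). GLO1 (−0.73) and DUG1 (0.68), named after their values were seen, completed them. The median was −0.14, and 0.89 with 9 members high and 0 low against those pairs (camera adjusted p = 0.279). Without replicate 3 none was called and the median was 0.0023, while without replicate 1 it was −0.37.

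Genes of NADPH supply, chaperones and the proteasome did not pass as lists. Without replicate 3, no more than 4 members were called in any of these lists or of those that follow. Of 18 pentose phosphate and NADPH genes, 7 lay high and 3 low (9 and 4 adjusted over the list alone), with ALD6 at 2.00 ± 0.30, IDP1 at 1.49 ± 0.54, TKL1 at 1.25 ± 0.49 and SOL4 at −1.30 ± 0.20 (SD, n = 3 each). The median was 0.54 (camera adjusted p = 0.302), but 0.17 with 3 high and 2 low when the scatter trend was removed, a setting chosen after the data were seen. Of 31 chaperone genes, 5 lay high and 2 low (4 and 2 adjusted over the list alone). SSA1 (1.17 ± 0.27) and HSP42 (1.07 ± 0.26) lay high, HSP104 (−0.87 ± 0.78) and CUR1 (−1.08 ± 0.84) lay low (SD, n = 3 each). The median was 0.14 (camera adjusted p = 0.499). Of 35 proteasome genes, 2 lay high and 3 low (1 and 2 adjusted over the list alone), among them RPN9 (1.12 ± 0.29), PRE2 (0.65, named after its value was seen), ECM29 (−1.23 ± 0.24), PRE1 (−0.82 ± 0.23) and PRE4 (−0.67 ± 0.31; SD, n = 3 each). The median was −0.10 (camera adjusted p = 0.323), and it ran from −0.23 without replicate 1 to 0.0078 without replicate 3.

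Transport and membrane lists had called members on both sides. Drug transporters had 4 high and 3 low of 25 (the same adjusted over the list alone), with DTR1 at 1.09 ± 0.07, YOR1 at −1.03 ± 0.55 and BPT1 at −0.88 ± 0.34 (SD, n = 3 each). The median was 0.17 (camera adjusted p = 0.588). The iron regulon had 3 high and 4 low of 32 (2 and 4 adjusted over the list alone), with FTH1 at 1.52 ± 0.41, SIT1 at 1.21 ± 0.44, TIS11 at −1.23 ± 0.53 and FIT2 at −0.80 ± 0.53 (SD, n = 3 each). The median was 0.06 (camera adjusted p = 0.866), and its sign turned with blocks centred (−0.095), a setting chosen after the data were seen. Ergosterol synthesis had 6 high and 2 low of 24 (the same adjusted over the list alone), with MVD1 at 1.33 ± 0.54, ERG13 at 1.27 ± 0.59, ERG10 at 1.00 ± 0.38 and ERG24 at −1.50 ± 0.72 (SD, n = 3 each). The median was 0.21 (camera adjusted p = 0.372). ERG6, given above as a neighbour of YAP1, was not in this list. The phosphate regulon had 2 high and 2 low of 19 (the same adjusted over the list alone), with VTC2 at 1.33 ± 0.14, VTC1 at 0.96 ± 0.37, PHM7 at −0.90 ± 0.14 and CTF19 at −0.84 ± 0.74 (SD, n = 3 each). The median was 0.23 (camera adjusted p = 0.669), but 0.0086 without replicate 2. The respiratory chain had 5 high and 3 low of 38 (1 and 1 adjusted over the list alone), with CYT1 at 1.08 ± 0.53, CYC1 at 0.77 ± 0.19, COX7 at −0.96 ± 0.62 and NDI1 at −0.78 ± 0.70 (SD, n = 3 each). The median was 0.18 (camera adjusted p = 0.481).

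Cell cycle and mating genes did not pass as lists on the full set of genes either. Cell cycle genes had 7 high and 2 low of 24 (9 and 4 adjusted over the list alone), led by the DNA polymerase gene POL1 at 1.58 ± 0.52, AMN1 at 1.21 ± 0.42, CTS1 at 1.14 ± 0.65 and the ribonucleotide reductase gene RNR1 at 0.93 ± 0.33 (SD, n = 3 each). Their median was 0.36 (camera adjusted p = 0.0668, and adjusted p = 0.647 with an estimated correlation). In a fit without ribosomal protein genes, chosen after the data were seen, this list passed (adjusted p = 0.0357). Pheromone and mating type genes had 3 high and 4 low of 22 (the same adjusted over the list alone), with FUS1 at 1.12 ± 0.37, HO at 0.85 ± 0.57, PRM1 at −1.69 and MF(ALPHA)1 at −0.84 ± 0.42 (SD, n = 3 each). Their median was 0.04 while their mean was −0.10 and camera's direction was low (adjusted p = 0.554). The sign of this median turned without replicate 1 (−0.22) or 3 (−0.14). Subtelomeric families had 8 high and 8 low of 42 (9 and 8 adjusted over the list alone), with PAU15 at 1.87 ± 0.78, COS2 at 1.82 ± 0.04, PAU3 at 1.55 ± 0.17 and PAU21 at 1.39 ± 0.87 (SD, n = 3 each). Their median was −0.01, their mean 0.07 and camera's direction low (adjusted p = 0.995). The sign of this median turned without replicate 1 (0.033) or 2 (0.059). None of the 7 measured Yap family genes passed, with 0 also when adjusted over the list alone: YAP7 lay at 0.54 ± 0.14 and YAP6 at −0.56 ± 0.25 (SD, n = 3 each). The median was −0.26 (camera adjusted p = 0.481).

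Genes often used as strain markers were examined because a marker that differs between the strains would stand out in every array. Of 9, 5 lay on the high side and 1 on the low side (5 and 2 adjusted over the list alone). LEU2 lay at 1.53 ± 0.35, LYS2 at 1.22 ± 0.37, URA3 at 1.17 ± 0.06, HO at 0.85 ± 0.57 and ADE2 at 0.66 ± 0.22, and MET17, a sulfur assimilation gene, at −1.27 ± 0.54 (SD, n = 3 each). HIS3 (−0.71 ± 0.79), TRP1 (−0.21 ± 0.04) and CAN1 (0.07 ± 0.39) did not pass (SD, n = 3 each). The median was 0.66 (camera adjusted p = 0.279). The labels used here do not give the markers of the strains.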

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

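All tests in this part were chosen after the result they bear on was seen, except the counts over the choices of sign.

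Spots without a gene symbol are not among the genes compared above, where some serve as a reference level. Many had ratios away from the array median, which does not show signal over background: of 959 such spot pairs, 489 passed the limma threshold when tested like genes, 68 of them on the high side and 421 on the low side. Outside the positions that are unnamed in every block, 53 of 671 pairs passed on the high side and 254 on the low side. At the 4 low positions, 152 of 192 pairs passed on the low side.

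The ribosomal protein genes lay on the high side of every array, with a list median of 2.07. A trend of the ratio with spot brightness left in the deposited values may account for part of this, since the glycolysis list, whose transcripts are also abundant, had a median of 0.94. A higher level of these transcripts in one strain remains open as well: the highest median among 10000 random lists of other genes matched on the scatter between repeated spots was 0.55, below the median of the ribosomal protein list. With the scatter trend removed, the list median was still 1.55 and 116 of 132 members were called high, while the calls over all genes went from 1581 to 1085, which argues against the scatter trend as the whole cause. That scatter is only a noisy stand-in for brightness and no array had its dyes swapped, so a strain difference cannot be told apart from a brightness or dye effect beyond that trend.

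Of 112 general stress, sulfate and methionine, and peroxide defence genes, 34 were called on the low side; the low calls of the 3 lists, 14, 13 and 9, were 2, 1 and 3 without replicate 3, and against the 4 low positions 2, 2 and 2 with 19, 23 and 26 high. Differences between printed blocks are argued against by the 29 of these 34 genes that were still called low after each block was centred. Spots with no measurable transcript stay open: the scatter between repeated spots of these 34 genes was 0.743 times that of the called pairs at the 4 low positions (95% bootstrap interval 0.597 to 0.898), but what those positions hold is not known, so this ratio decides nothing. Loss of Yap1 may contribute, but the median over all members of the 3 lists was −0.19 with members on both sides, and with a single dye orientation a strain difference cannot be told apart from a dye effect.

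Averaged over its 2 spots, YAP1 itself lay on the low side of every array, as a deleted gene would if the ratio were mutant over wild type. Its mean stood at percentile 75 of the pairs at the 4 low positions, within their range. The percentiles on the 3 arrays were 19.8, 97.9 and 60.4, so on replicate 2 YAP1 lay above nearly all of them. What those positions hold is not known, so this level does not show that the YAP1 spots lacked signal. Only if they lacked it in both strains would the value say nothing of the direction. Whether wild type transcript was measured there is not known, so by this value the direction of the ratio, mutant over wild type or the reverse, cannot be told. The Yap1 target list leaned to the low side without settling it: 9 of its genes were called low and 4 high, against 686 and 882 of the other called genes (Fisher's exact test, two-sided, p = 0.0906, odds ratio 2.89). By the same Fisher's exact test the odds ratio was 4.73 with array weights (p = 0.0125), 5.5 with blocks centred (p = 0.00632), 5.73 with the scatter trend removed (p = 0.00361), 5.88 without replicate 3 (2 low and 2 high, p = 0.107) and 21.9 on the 4 low positions (1 low and 21 high, p = 0.0515), but 2.32 centred outside the ribosomal lists (p = 0.160) and 1.97 without ribosomal protein genes (p = 0.269), and the test takes genes as independent, so the direction stays open.

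The signs of 3 arrays can be chosen in 4 ways, too few for a share under 0.05. The real signs gave 1581 genes (1 of the 4 choices gave as many) and the highest of the others gave 0 genes. For gene lists the real signs gave 7, and 2 of the 4 choices gave as many, the highest of the others being 9 with replicate 2 turned.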

How the results depend on the processing

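The count of 1581 called genes (886 high, 695 low) stayed within 1.5 times under scaling (1524), centring on genes outside the ribosomal lists (1575), robust eBayes (1641), array weights (1535), the median over spots (1582), every spot on its own (1357), and an adjusted p under 0.1 (2097). It also did so in settings chosen after the data were seen, with blocks centred (1471), without ribosomal protein genes (1468), and with the scatter trend removed (1085, 612 high and 473 low). With 2 or more arrays required it was identical, as no value was missing, so that setting tests nothing. With 1 replicate left out the counts ran from 323 (without replicate 3) to 1443 (without replicate 1), from 275 to 826 on the high side and from 48 to 617 on the low side. Without replicate 2 they were 889, 538 and 351. Each of these fits had 2 arrays, so the number of arrays does not account for the differences between them. Replicate 3 had the highest array weight (1.25, against 0.949 and 0.842 for replicates 1 and 2). It also had the smallest interquartile range over genes (0.741, against 1.03 and 1.19). Beyond that, the cause of the lower counts was not tested. As deposited, 5260 genes passed, 2 high and 5258 low, a share of 0.038% high against 56.0%, and centred on the 4 low positions, chosen after the data were seen, 4180 passed, 4170 high and 10 low (99.8% high), because the zero point moved. Without replicate 3 the high share was 85.1%, for which the cause was not tested. An unmoderated one-sample test passed 1 gene after adjustment, 0 high and 1 low, with 1252 genes at an unadjusted p under 0.05, as 3 arrays leave it few degrees of freedom. An adjusted p under 0.01 left 802 (542 high, 260 low), a mean of at least 1 unit 707 (486 and 221), and at least 1 unit on each array with no test 302 (260 and 42). For YAP1 the mean ran from −1.09 to −0.48 with a replicate left out (adjusted p from 0.0101 without replicate 2 to 0.226 without replicate 1). Its call was lost in the unmoderated test (−0.80, adjusted p = 0.332) and with the scatter trend removed (−0.27, adjusted p = 0.501), and its sign changed on centring on the 4 low positions (0.23) and when all signs were turned (0.80, by construction). Apart from the zero point and sign, the cause was not tested. Gene lists past camera numbered 7, and 5 as deposited, 9 scaled, 6 to 11 with a replicate left out (11 without replicate 2), 8 with blocks centred, 9 on the 4 low positions, 12 with the scatter trend removed (adding Yap1 targets, peroxide and thiol defence, oxidoreductases, sulfate and methionine, and proteasome, all low; with an estimated correlation none of the 26 passed in that setting, the smallest adjusted p being 0.336), 7 without ribosomal protein genes (that list gone, cell cycle added), 7 without members of other lists, 0 with an estimated correlation and 4 by fry (ribosomal proteins, ribosome biogenesis, copper and zinc, and arsenite detoxification, the last at an adjusted p of 0.0235). With an estimated correlation, camera takes its degrees of freedom from the 3 arrays and not from the number of genes, so hardly any list can pass. For ribosomal proteins and for copper and zinc the estimated correlation was also below the preset one and so did not remove their calls. For the other settings the cause was not tested. Beyond the list calls given with the results, peroxide defence and oxidoreductases passed, low against the other genes, when scaled (adjusted p = 0.0493 each), without replicate 2 (0.00978 and 0.0193) and with the scatter trend removed (0.00605 and 0.0148), defence also without replicate 1 (0.0292) and with values centred on the 4 low positions (0.0346), and oxidoreductases without members of other lists (0.0398). Sulfate and methionine passed without replicate 2 (0.0193) and with the scatter trend removed (0.0310). The lowest correlation between arrays was 0.623, 0.560 without ribosomal protein genes and 0.081 without called genes, a choice that removes the shared signal. Of the named genes other than YAP1, 54 lost their call without replicate 3, 10 without replicate 1 and 10 without replicate 2, 105 in the unmoderated test, 22 with the scatter trend removed and 8 with blocks centred, all keeping their direction. A further 13 as deposited and 17 on the 4 low positions lost their call with no change of side, beside the changes of side listed below. No paired analysis was possible because the arrays form a single group and each already compares both strains. The deposited table used here gives no signal over background, so what low signal limits is not known.

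The sign of 50 named genes on the high side after centring, called or not, was negative as deposited, because most ratios lie below 0 before centring: ALD6 −0.0030, HHT2 −0.048, PAU15 −0.13, LYS21 −0.17, COS2 −0.18, AAD4 −0.19, CDC19 −0.24, SAH1 −0.26, FBA1 −0.28, TDH2 −0.29, ENO2 −0.34, POL1 −0.42, BAT1 −0.42, PAU3 −0.45, THR4 −0.46, LEU2 −0.47, FTH1 −0.48, LEU1 −0.49, IDP1 −0.51, NOP56 −0.59, GAR1 −0.59, PAU21 −0.61, FLR1 −0.61, MVD1 −0.67, VTC2 −0.67, NSR1 −0.68, ERB1 −0.70, ERG13 −0.73, TKL1 −0.75, LYS2 −0.78, AMN1 −0.79, SIT1 −0.79, URA3 −0.83, SSA1 −0.83, CTS1 −0.86, FUS1 −0.88, RPN9 −0.88, ERG6 −0.91, DTR1 −0.91, CYT1 −0.92, HSP42 −0.93, ERG10 −0.996, VTC1 −1.04, RNR1 −1.07, HO −1.15, CYC1 −1.23, ADE2 −1.34, YAP7 −1.46, HOG1 −1.80 and CAN1 −1.93. Centred on the 4 low positions, 22 named genes other than YAP1 changed to the high side, because that centring raises all values: FPS1 0.98, TRP1 0.82, ARR1 0.77, YAP6 0.47, YCF1 0.45, PRE4 0.36, HIS3 0.31, ARR3 0.29, DUG3 0.28, STR2 0.26, NDI1 0.25, FIT2 0.22, PRE1 0.21, MF(ALPHA)1 0.19, CTF19 0.19, GIS4 0.18, HSP104 0.16, BPT1 0.15, PHM7 0.13, CRS5 0.11, COX7 0.065 and YOR1 0.0020. Some genes near 0 that were not called also changed side: CAN1 and FPS1 without replicate 2, CAN1 with blocks centred and ARR1 with the scatter trend removed.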

Other observations

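The families in this part and their tests were chosen after the data were seen.

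Other genes of protein synthesis lay with the ribosomal proteins. Of 20 translation factor genes, 19 were called on the high side and 0 on the low side, with a median of 1.46 relative to the array median (camera adjusted p = 4.63e-12, and adjusted p = 0.243 with an estimated correlation). TMA19 (2.56 ± 0.32), the elongation factor gene EFT1 (2.09 ± 0.68) and HYP2 (2.05 ± 0.44), which encodes the hypusine-containing factor, led them (SD, n = 3 each). Of 18 tRNA synthetase genes, 12 were called high and 0 low, with a median of 1.06 (camera adjusted p = 1.06e-06, and adjusted p = 0.243 with an estimated correlation), led by the leucyl and asparaginyl enzymes CDC60 (1.79 ± 0.53) and DED81 (1.58 ± 0.50; SD, n = 3 each). The mitochondrial ribosomal proteins did not share this position: of 65 genes, 2 were called high and 7 low, and the median was −0.17 (camera adjusted p = 0.149). Of 13 vacuolar ATPase genes, 7 were called high and 1 low (median 0.67, camera adjusted p = 0.0272, and adjusted p = 0.259 with an estimated correlation).

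Autophagy and sporulation genes lay toward the low side of the array median. Of 36 autophagy genes, 10 were called low and 1 high, with a median of −0.35 (camera adjusted p = 0.0131, and adjusted p = 0.243 with an estimated correlation). ATG8, for the ubiquitin-like protein of the autophagosome membrane, lay at −1.28 ± 0.33, and ATG16 at −1.14 ± 0.31 (SD, n = 3 each). Of 29 sporulation genes, which are mostly silent in growing cells, 8 were called low and 1 high, with a median of −0.48 (camera adjusted p = 0.00306, and adjusted p = 0.243 with an estimated correlation), among them SPS2 (−1.10 ± 0.23) and SPO11 (−0.97 ± 0.10; SD, n = 3 each). Hexose transporters (median −0.14), peroxisome biogenesis (−0.14), nucleoporins (−0.20), RNA polymerase II subunits (0.41) and cell wall mannoproteins and glucanases (0.29) did not pass camera (adjusted p from 0.139 to 0.883).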
